A study of Mus musculus with 4 samples.

How the data were processed

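Transcripts were measured in 4 livers of C57BL/6 mice, 2 from the wild type and 2 from animals with the Ezh2 mutation on both copies. Livers were flash frozen, total RNA was extracted with TRIzol and libraries were made by the sequencing provider BGI, per the labels' protocols. Genotype and replicate number were taken from the labels, which give no sex, age, hour of collection, litter or batch. HISAT, Bowtie2, RSEM and the mouse genome build mm10 are named per the submitters' processing notes, without versions. The step in which each aligner was used, read trimming, read length, pairing of reads and the strand setting are not given in the sources used here.

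Each liver had 1 deposited table of RefSeq transcripts with their Entrez gene numbers. Its expected counts, the estimated counts that RSEM assigns to each transcript and that need not be whole, were not normalized, per the file headers and the values in the tables. Its FPKM values were scaled by the authors to transcript length and library depth, per the file headers. The smallest FPKM listed was 0.01 in each table, and a transcript missing from a table was set to 0. The 4 tables held between 19723 and 20492 transcripts, 23978 in any liver and 16441 in all 4.

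Expected counts were summed over the transcripts of each gene and rounded to whole numbers, which gave 17543 genes, of which 13505 had 1 transcript and 4038 several. Symbols and coordinates came from NCBI RefSeq's gene table of GRCm38.p6, the same assembly as mm10, by Entrez number. This named 17502 genes (99.8%). The other 41, at 0.0377% to 0.0428% of the counts of a liver, were kept under their Entrez numbers. They passed through the same filter, library sizes and tests as the named genes. RSEM divides reads that match several genes, so that members of families with near-identical copies (Mup, Cyp2a, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Sult2a, Sult3a, Ugt2b, Serpina1, Serpina3, H2 and others) are uncertain one by one. Overlapping and antisense genes are uncertain too, because the strand setting is not known.

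The main test was edgeR 4.0.16's quasi-likelihood F test in R 4.3.3, with TMM factors (0.896 and 1.055 in the wild type, 1.014 and 1.043 in the mutants), genes kept by filterByExpr and genotype as the only term, on 2 residual degrees of freedom. Adjusted p values are Benjamini-Hochberg values over the 12837 genes tested, with a threshold of 0.05, and the common biological coefficient of variation was 0.217. Standard errors of log2 fold changes were computed from the fold change and its F value. CPM are counts scaled to the TMM library sizes, and errors are SDs over the 2 livers of a genotype. Adjustment over a list alone used the p values of that list's tested members. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over lists. A fold against a genotype with 0 reads was computed against a floor of 3 reads over its 2 livers. For the genes given as such bounds, a transcript at the smallest listed FPKM would hold between 0.148 and 2.06 reads over the 2 livers, which is under that floor. Ratios of genes with 1 to 3 reads in a genotype carry exact 95% Clopper-Pearson intervals. Floors and such intervals cover counting error only.

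The 49 gene lists, the named gene rule, the main test and the other settings below were fixed before the data were examined. The lists were written from textbook knowledge and hold 1267 symbols, of which 1227 matched a current symbol, 37 a synonym and 3 neither. Of the matched genes 1170 were in the tables. The lists overlap, and 46 had enough tested members. The named genes are the 12 with the largest rise and the 12 with the largest fall among those called, without overlap between the genotypes, at a mean of at least 1 CPM in the higher genotype and with a proper symbol. To these come Ezh2, the PRC2 and sex chromosome lists, and from every list up to 4 members with the smallest p. Clock, Nr1d1 and Uba1y fall outside this rule and were chosen after their values were seen, as were the genes that open the part on other observations. Some genes that the rule selects are not reported here.

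The other settings were RLE, upper-quartile and total-count scaling in edgeR, DESeq2 1.42.0, limma-voom, limma with trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1 in a genotype, no filter beyond 1 read in any liver, a mean of at least 1 CPM, the replicate number as a block, and leaving out each liver in turn. Without a liver, 1 genotype has 1 liver, which is assumed to vary as the livers of the other genotype do. A fit without the genes on the sex chromosomes, in the sex-biased lists and in the clock lists was added after the data were seen. Other tests used Python 3.11.15 with scipy 1.17.1 and pandas 2.3.3. Replicates were compared by chi-square over genes with at least 10 reads.

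The edgeR steps were tested on simulated counts of this comparison, drawn from the real means and library sizes with the same biological variation for every gene. Only genes at a mean of at least 1 CPM were changed. Variation in the real livers differed by gene, so the shares given next need not hold there. With 200 genes changed 4-fold among 12816 tested, 98% of these were called, and 4.39% of the 205 calls were false. With 200 genes changed 2-fold among 12825, 13% were called, and 7.14% of the 28 calls were false. With no gene changed, edgeR called 0 of 12809, and 4.93% of these had an unadjusted p under 0.05.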

Results

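The series measured the transcripts of mouse liver by RNA sequencing in wild-type C57BL/6 mice and in C57BL/6 mice carrying a point mutation, K307R, on both copies of Ezh2. Ezh2 is the catalytic subunit of Polycomb repressive complex PRC2, which methylates lysine 27 of histone H3. The comparison asks which liver transcripts differ in level between the genotypes. Each genotype had 2 livers, given in the labels as replicates 1 and 2. The labels give no sex, age or hour of collection for any animal, and do not say that the replicates came from separate animals, so that p values measure the spread between these samples. The deposited expected counts summed to 19289715 and 20044832 in the wild-type livers and to 18602928 and 18749610 in the mutant livers. Between 15632 and 16172 genes were listed per liver, and 12837 genes had enough reads to be tested. The correlation of log2 CPM, reads scaled to a common library size, across genes was 0.973 between the wild-type livers and 0.978 between the mutant livers, against 0.942 to 0.944 between livers of different genotypes. The counts of replicate livers differed by more than sampling noise (chi-square per gene 94.1 in the wild type and 51.4 in the mutants), so neither pair was treated as a single library deposited under both numbers, which does not show that they came from separate animals.

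Ezh2 itself (Entrez gene 14056, chromosome 6 from 47530274 to 47595270, mm10) was a low transcript in these livers. Its level was 3.64 ± 0.405 CPM in the wild type and 3.0 ± 0.630 CPM in the mutants (mean ± SD, n = 2 each). The log2 fold change was -0.28 (SE 0.33), with a 95% interval of -1.04 to 0.48 and an edgeR adjusted p of 0.737. A point mutation need not alter the level of its transcript, and the gene counts do not resolve bases, so this value does not check the genotype labels. Among the 15 PRC2 subunits and H3K27 demethylases, 1 fell and 0 rose. The gene that fell was Uty, which lies on the Y chromosome. Ezh1, the paralogue of Ezh2, had a log2 fold change of 0.48 (edgeR adjusted p = 0.289), Suz12 one of -0.32 (0.518) and Eed one of -0.15 (0.762). Kdm6a, the X-linked H3K27 demethylase related to Uty, had a log2 fold change of 0.82 (edgeR adjusted p = 0.0953). Adjusted over the list alone, 1 member rose and 2 fell. As a group the list did not pass the camera test (adjusted p = 0.0697), nor without the sex-chromosome, sex-biased and clock genes (0.481), though it was lower with no filter on low counts, Uty included (0.0485).

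The sex-chromosome transcripts separated the genotypes without overlap. Xist, the X-linked RNA that silences an X chromosome in female cells (Entrez gene 213742, chromosome X from 103460373 to 103483233), had 6 and 6 reads in the wild-type livers and 6172 and 11201 reads in the mutant livers. Its level rose from 0.316 ± 0.0447 to 450 ± 174 CPM (n = 2 each), a log2 fold change of 10.46 (SE 0.47, edgeR adjusted p = 1.82e-04). Xist overlaps its antisense RNA Tsix, and whether the counting used strand is not given in the sources used here. The Y-linked genes went the other way. Ddx3y (chromosome Y from 1260715 to 1286628) was at 60.0 ± 10.7 CPM in the wild type, Eif2s3y (1010562 to 1049134) at 52.1 ± 8.96 CPM, Uty (1085187 to 1245773) at 14.2 ± 5.18 CPM and Kdm5d (897566 to 943813) at 13.1 ± 1.56 CPM. Together these 4 genes had 2732 and 2551 reads in the wild-type livers and 0 and 0 in the mutant livers. Against a floor of 3 reads over a genotype, Ddx3y was at least 768-fold lower in the mutants, Eif2s3y at least 667-fold, Uty at least 182-fold and Kdm5d at least 167-fold. Uba1y, the remaining Y-linked gene tested, which has an X-linked relative, had 30 and 26 reads in the wild type and 39 and 41 in the mutants (edgeR adjusted p = 0.592). Both wild-type livers thus carried the transcripts typical of males and both mutant livers those typical of females, so that genotype and sex-chromosome pattern coincided in all 4 livers. No comparison within 1 sex-chromosome pattern could be made.

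**Figure D1:**
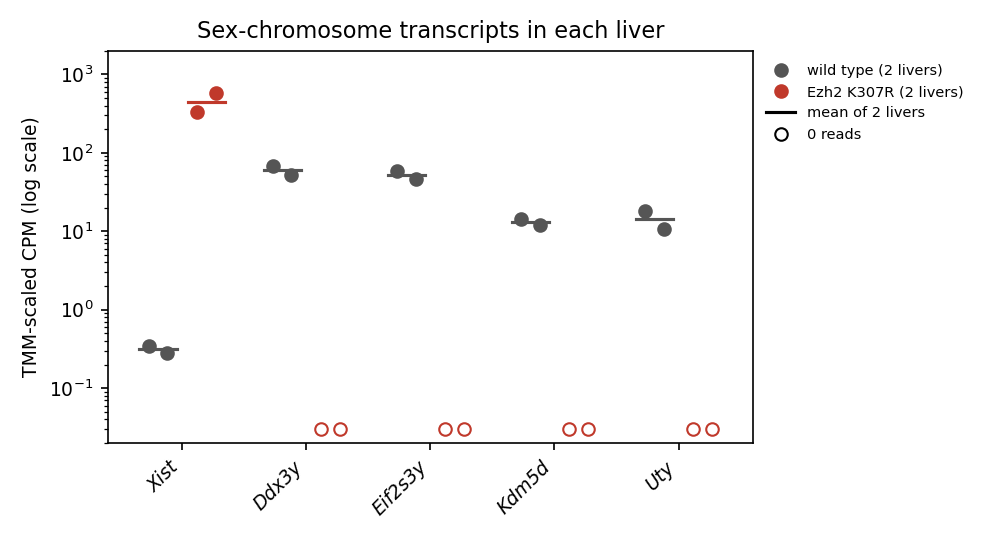
TMM-scaled CPM (log axis) of Xist and 4 Y-linked genes in each liver; filled points are livers, horizontal lines are means of 2 livers and open points mark 0 reads. Xist sits at 0.284 and 0.347 CPM in the wild type and at 327 and 573 CPM in the mutants, and Ddx3y, Eif2s3y, Kdm5d and Uty have reads in the wild type and 0 in the mutants.

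Across the genome, 178 genes were higher and 189 lower in the mutant livers by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The called genes had a median absolute log2 fold change of 1.87, and 360 of the 367 differed by more than 2-fold. The named genes with the largest rises were mostly sulfotransferases and cytochromes P450, several of them known for high levels in female mouse liver. Cyp3a41a rose by 11.30 (SE 1.32) on the log2 scale, from 1.37 ± 1.94 to 3602 ± 1110 CPM (n = 2 each). Sult2a1 rose by 10.19 (SE 1.09), Cyp3a41b by 9.60 (SE 1.35), Cyp2b13 by 9.50 (SE 0.77), Sult2a2 by 8.98 (SE 0.80), A1bg, a plasma glycoprotein, by 8.88 (SE 1.07) and Cyp3a16 by 8.35 (SE 0.60). The mutant livers themselves differed widely in these genes, with 374 and 63.7 CPM of Sult2a1, 594 and 81.6 CPM of Cyp3a41b and 353 and 97.7 CPM of Sult2a2. Without mutant replicate 1 the log2 fold changes were 8.41 for Sult2a1, 7.56 for Cyp3a41b, 7.78 for Sult2a2, 7.97 for A1bg and 7.51 for Cyp3a16, and without mutant replicate 2 they were 10.96 for Sult2a1, 10.41 for Cyp3a41b and 9.64 for Sult2a2. Without wild-type replicate 1 they were 10.35 for Cyp3a41a, 8.63 for Cyp2b13 and 8.01 for A1bg, and without wild-type replicate 2 they were 8.50 for Cyp3a41b and 9.88 for Sult2a2. Sult3a1 had 1 read in the wild type against 5691 in the mutants, a ratio of 5694 with a 95% counting interval from 1022 to 224900, and Tafa2, which encodes a secreted chemokine-like protein, had 1 against 270 reads, a ratio of 270.1 (48.1 to 10710). Sult3a2 was at least 125-fold higher and the ribosomal protein retrogene Rps27rt at least 83.9-fold higher. Xist completes these 12. The largest falls, after the 4 Y-linked genes, included genes known for high levels in male liver. Cyp4a12a, an arachidonic acid hydroxylase, fell with a log2 fold change of -7.91 (SE 1.25), as did Cyp4a12b (-7.70, SE 0.98), the glucuronosyltransferase Ugt2b38 (-7.53, SE 1.09), Cib3 (-5.78, SE 0.34), the trefoil peptide gene Tff3 (-5.67, SE 0.95), Cyp2d9 (-5.52, SE 0.59) and Serpina4-ps1 (-5.36, SE 0.44). Without wild-type replicate 1 the values were -5.74 for Cyp4a12a, -6.38 for Cyp4a12b, -5.54 for Ugt2b38, -4.47 for Cyp2d9 and -6.44 for Tff3, and without wild-type replicate 2 they were -8.74, -8.39, -8.34, -6.12 and -3.85. Without mutant replicate 1 they were -6.98 for Cyp4a12a and -6.75 for Cyp4a12b. Tff3 lost its call without mutant replicate 1 (edgeR adjusted p = 0.0555) or 2 (0.0719). Cspg5, a chondroitin sulfate proteoglycan, had 95 reads in the wild type and 1 in the mutants, a ratio of 94.9 (16.6 to 3789), a call lost without mutant replicate 1 (edgeR adjusted p = 0.0531). Reads of the Cyp3a, Cyp2b, Cyp4a12, Sult2a, Sult3a and Ugt2b members could have been divided between near-identical copies, so single members of these families are uncertain. Those of the retrogene Rps27rt could likewise have been divided with its parent gene, which its fold bound does not cover.

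With total-count scaling the split was 188 higher and 124 lower, that is 60.3% higher against 48.5%. The counts were 327 higher and 393 lower without wild-type replicate 1, 302 and 305 without wild-type replicate 2, 167 and 122 without mutant replicate 1, and 117 and 94 without mutant replicate 2, and 79 higher and 55 lower genes kept their call whichever liver was left out. Among called genes named in the text with more than 3 reads left in each genotype, the fold moved by over 1.5 times for 17 of 98 without wild-type replicate 1, 16 of 94 without wild-type replicate 2, 10 of 98 without mutant replicate 1 and 6 of 97 without mutant replicate 2. After removal of the genes on the X and Y chromosomes and of the sex-biased and clock lists, an alternative chosen after the data were seen, 156 genes were higher and 168 lower among 12346 tested. Of these, 298 were among the 367 called with all genes.

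The lists of liver genes known to differ between the sexes, fixed before the data were examined, contained 46 of the 367 calls. These were 52.3% of the 88 list members tested, against 2.52% of the 12749 other genes (Fisher's exact test, two-sided, p = 4.65e-48, with genes not independent). Of 48 female-biased genes, 23 rose and 1, the lipoprotein lipase gene Lpl (-2.32), fell, and 33 rose and 2 fell when adjusted over the list alone. The median log2 fold change was 2.77 (camera adjusted p = 2.98e-50, adjusted p = 0.419 with an estimated correlation). Of these calls, 22 of the 23 rises were kept without mutant replicate 1, and Lpl, at -1.65 without wild-type replicate 2, was not kept without mutant replicate 2 (edgeR adjusted p = 0.0646). Cyp2c38, an arachidonic acid epoxygenase, rose by 2.74 (SE 0.22) and Prlr, the prolactin receptor, by 2.08 (SE 0.28). Of 35 male-biased genes, 17 fell and 0 rose, and 27 fell when adjusted over the list alone. The median was -2.77 (camera adjusted p = 2.48e-35, adjusted p = 0.562 with an estimated correlation). Serpina1e, an alpha-1-antitrypsin of male mice, fell from 12238 ± 4068 to 767 ± 213 CPM (n = 2 each), and Selenbp2, a selenium-binding protein, fell by 3.87 (SE 0.41), with a value of -3.28 without wild-type replicate 1. Without mutant replicate 1, 11 of the 17 male-biased calls were kept, 13 without mutant replicate 2 and 16 without wild-type replicate 1. The list of 5 sex chromosome genes had 1 rise and 4 falls, in the whole test and when adjusted over the list alone, with a median of -11.09 in the fit and -7.51 with the genes at 0 reads set at their bound (camera adjusted p = 1.97e-28, adjusted p = 0.419 with an estimated correlation).

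Clock genes differed between the genotypes in opposite directions according to their known peak time. Of 15 clock and output genes that peak around dusk, 4 fell and 1 rose, and 11 fell and 2 rose when adjusted over the list alone. Ciart, a repressor of the clock activators, fell (log2 fold change -5.16, SE 0.34), as did the deubiquitinase gene Usp2 (-3.20, SE 0.26), the cell cycle kinase gene Wee1 (-2.05, SE 0.27) and the period gene Per2 (-1.97, SE 0.26). Nr1d1, the nuclear receptor that represses Arntl, rose by 1.24 (SE 0.19). The list median was -1.35 (camera adjusted p = 9.84e-13, adjusted p = 0.419 with an estimated correlation). Of 7 genes that peak around dawn, 4 rose and 1 fell, likewise over the list alone. Arntl, the core clock activator also called Bmal1, rose by 3.97 (SE 0.39), from 1.14 ± 0.0594 to 18 ± 8.04 CPM, Nfil3 by 2.43, Npas2 by 4.56 and Clock by 1.6. The median was 1.6 (camera adjusted p = 2.40e-05, adjusted p = 0.419 with an estimated correlation). Without mutant replicate 2, 2 of the 4 dawn rises kept their call, and Npas2 (edgeR adjusted p = 0.0965) and Clock (0.126) did not. Npas2 was at 3.68 without wild-type replicate 1.

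Genes of fatty acid and triglyceride synthesis were lower in the mutant livers. Of 28 tested, 7 fell and 0 rose, and 11 fell when adjusted over the list alone. Acaca, the acetyl-CoA carboxylase that commits carbon to fatty acids, fell from 391 ± 4.41 to 121 ± 19.5 CPM (log2 fold change -1.69, edgeR adjusted p = 0.0127). Acly, which makes cytosolic acetyl-CoA from citrate (-2.03, SE 0.38), Lpin1, a phosphatidate phosphatase (-2.19, SE 0.32), and the triokinase gene Tkfc (-1.40, SE 0.24) also fell. The list median was -0.78 (camera adjusted p = 1.11e-08, adjusted p = 0.562 with an estimated correlation). Of 25 glycolysis and glycogen genes, 4 fell and 0 rose (8 and 1 adjusted over the list alone). These were the liver glycogen synthase gene Gys2 (-1.53), Gpi1 (-1.34), Pfkfb1 (-1.39), which lies on the X chromosome, and the pyruvate kinase gene Pklr (-1.73), with a list median of -0.55 (camera adjusted p = 1.18e-04, adjusted p = 0.562 with an estimated correlation). Without mutant replicate 2, 0 of the 7 lipid synthesis calls and 0 of the 4 glycolysis calls were kept. Without mutant replicate 1, 6 and 2 were kept, and without wild-type replicate 2, 3 of the 4 glycolysis calls. Acly was at -2.70 without mutant replicate 1. Targets of PPARA, the fatty acid-activated nuclear receptor, and fatty acid oxidation genes moved the other way. Of 39, 7 rose and 1 fell (13 and 1 adjusted over the list alone). Cd36, a fatty acid transporter, rose by 2.93 (SE 0.33), the acyl-CoA thioesterase gene Acot3 by 4.64 (SE 0.55), Pdk4, an inhibitor of pyruvate dehydrogenase, by 3.06 (SE 0.47) and Aldh3a2 by 1.66 (SE 0.26), and Cyp4a12a was the member that fell. Cd36 and Acot3 are also members of the female-biased list, and Cyp4a12a of the male-biased list. Without wild-type replicate 2 the values were 3.53 for Cd36 and 5.73 for Acot3, without wild-type replicate 1 Acot3 was at 4.05, and without mutant replicate 2 Pdk4 was at 2.21. Cyp4a12a was at -5.74 and -8.74 without wild-type replicates 1 and 2 and at -6.98 without mutant replicate 1. The median was 0.48 (camera adjusted p = 6.20e-07, adjusted p = 0.638 with an estimated correlation), 4 of the 7 rises kept their call without mutant replicate 2, and outside the sex and clock lists 5 of 34 members rose. Both mutant livers, in which these groups differed, also carried the female-type sex-chromosome transcripts (Xist log2 fold change 10.46) and the shifted clock genes (Arntl 3.97).

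**Figure D2:**
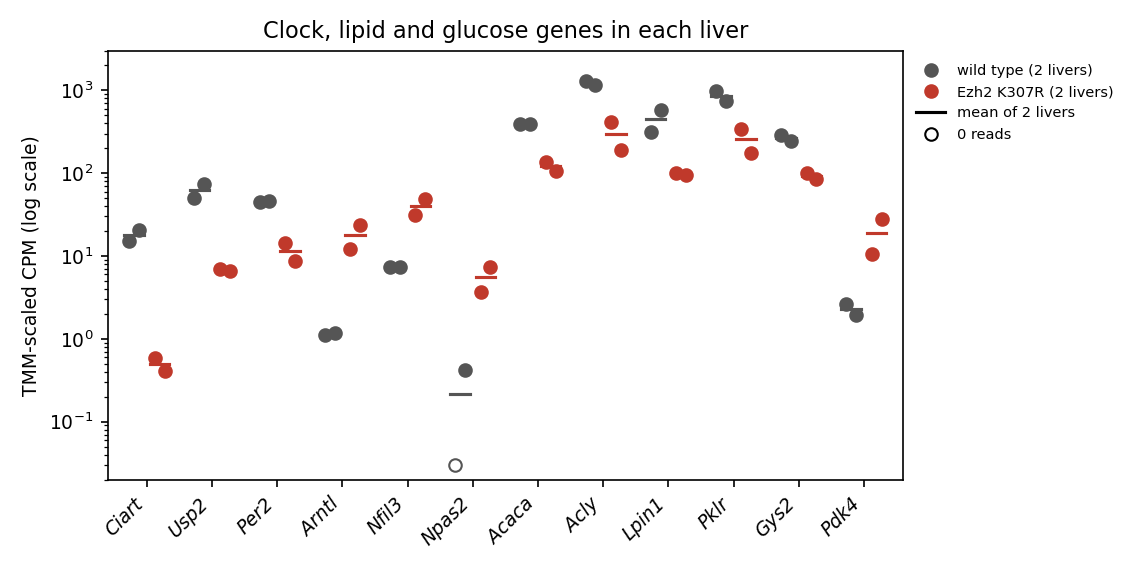
TMM-scaled CPM (log axis) of 6 clock genes and 6 genes of lipid and glucose metabolism in each liver; filled points are livers, horizontal lines are means of 2 livers and the open point marks 0 reads. Arntl is at 1.1 and 1.18 CPM in the wild type and at 12.3 and 23.7 CPM in the mutants, and Acaca is at 394 and 388 CPM against 135 and 108 CPM.

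Other metabolic lists showed fewer calls. Of 25 cholesterol synthesis and uptake genes, 2 fell and 0 rose, likewise over the list alone, among them the lanosterol synthase gene Lss (-1.07), and the list did not pass the camera test (median 0.09, adjusted p = 0.499). The call of Lss was not kept without wild-type replicate 2 (edgeR adjusted p = 0.0773), mutant replicate 1 (0.107) or mutant replicate 2 (0.114). Of 22 gluconeogenesis and fasting genes, Irs2, the insulin receptor substrate, rose by 3.13 (SE 0.50) and Lpin1 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.0552). The log2 fold change of Irs2 was 2.37 without mutant replicate 2 and 3.82 without wild-type replicate 1. The call of Lpin1 was not kept without mutant replicate 2 (edgeR adjusted p = 0.053). This list was lower without wild-type replicate 2 (camera adjusted p = 0.0466), with limma-voom (0.0357), on log2(FPKM + 1) (0.0401) and with no filter (0.0362). Of 28 bile acid genes, the efflux pump gene Abcc4 rose by 2.55 (4 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.245), a call not kept without mutant replicate 1 (edgeR adjusted p = 0.128) or replicate 2 (0.088), with a value of 3.62 without wild-type replicate 2. The bile acid list was higher without wild-type replicate 1 (camera adjusted p = 0.0202). Slco1a1, the organic anion transporter of male liver, had a log2 fold change of -2.77 (edgeR adjusted p = 0.0557) and was called without wild-type replicate 1 (-1.87, 0.0166), wild-type replicate 2 (-3.32, 2.93e-04) or mutant replicate 2 (-3.71, 0.0236). Of 33 urea cycle and amino acid genes, Gldc rose by 1.18 and Oat by 2.11 (4 and 0 adjusted over the list alone, camera adjusted p = 0.245), and neither kept its call without mutant replicate 2 (edgeR adjusted p = 0.0779 and 0.0877), nor Gldc without wild-type replicate 1 (0.0524). The urea cycle list was higher without mutant replicate 2 (camera adjusted p = 0.0372). Of 24 lipoprotein genes, the phospholipid transfer protein gene Pltp rose by 2.50 (SE 0.25, 2 and 0 adjusted over the list alone, camera adjusted p = 0.0608). The lipoprotein list was higher without mutant replicate 2 (camera adjusted p = 0.0435), with total-count scaling (0.0433), on log2(FPKM + 1) (0.0401), with no filter (0.0397) and without the sex and clock genes (0.0465). All 70 nuclear-encoded oxidative phosphorylation genes had a log2 fold change below 0, with a median of -0.35, but 0 passed edgeR's gene test, in the whole test or over the list alone. At an unadjusted p under 0.05 there were 11, DESeq2 called 1 lower and limma-voom 0. Ndufa8 had the smallest p (log2 fold change -0.88, edgeR adjusted p = 0.0625). The list as a group was lower (camera adjusted p = 1.22e-06, adjusted p = 0.754 with an estimated correlation). These genes also moved together between the 2 wild-type livers. Their median log2 ratio was -0.25 for replicate 2 over 1 (on CPM + 1, 61 of 70 lower in replicate 2).

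Xenobiotic metabolism genes rose as a group, mostly through members of the female-biased list. Of 42, 12 rose and 0 fell (18 and 2 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 8.10e-17, adjusted p = 0.419 with an estimated correlation). Among the 29 members outside the sex and clock lists, 3 rose and the list no longer passed the test (camera adjusted p = 0.0786). Without wild-type replicate 2, 11 of the 12 rises were kept, and 11 without mutant replicate 2. Of 29 glutathione and NRF2 target genes, 4 fell and 1 rose (8 and 1 adjusted over the list alone). Gstp1, a glutathione transferase known for higher levels in male mice, fell from 1979 ± 1030 to 265 ± 64.0 CPM, Gsta1 fell by 4.40 (SE 0.79) and Gstt3 rose by 1.65. Gsta1 was at -2.64 without wild-type replicate 2 and -5.17 without wild-type replicate 1, and Gstp1 at -2.24 without wild-type replicate 1 against -2.90. The list passed the test (median -0.15, camera adjusted p = 0.0253, adjusted p = 0.578 with an estimated correlation), but not without the sex and clock genes (0.0614), without wild-type replicate 2 (0.082), without mutant replicate 2 (0.200), with limma-voom (0.114) or on log2(FPKM + 1) and log2(FPKM + 0.1) (0.136 and 0.143). Of the 4 falls, 3 kept their call without mutant replicate 1 and 1 without mutant replicate 2. Of 20 major urinary proteins, pheromone carriers secreted by the liver, 1 fell, Mup20, also called darcin (-5.0, SE 0.57). When adjusted over the list alone, 7 fell and 1 rose. Mup20 was at -3.97 without wild-type replicate 1 and at -5.60 without wild-type replicate 2. The family took 4.48% of all counts in wild-type replicate 1, 0.904% in wild-type replicate 2, and 1.27% and 1.46% in the mutants. Its median was -1.19 (camera adjusted p = 0.0058, adjusted p = 0.778 with an estimated correlation), and without wild-type replicate 1 the test gave the opposite direction (0.00403). It did not pass with limma-voom (0.0724), with the replicate number as a block or without the sex and clock genes (0.357). The copies of this family are near-identical, and single members are uncertain.

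**Figure D3:**
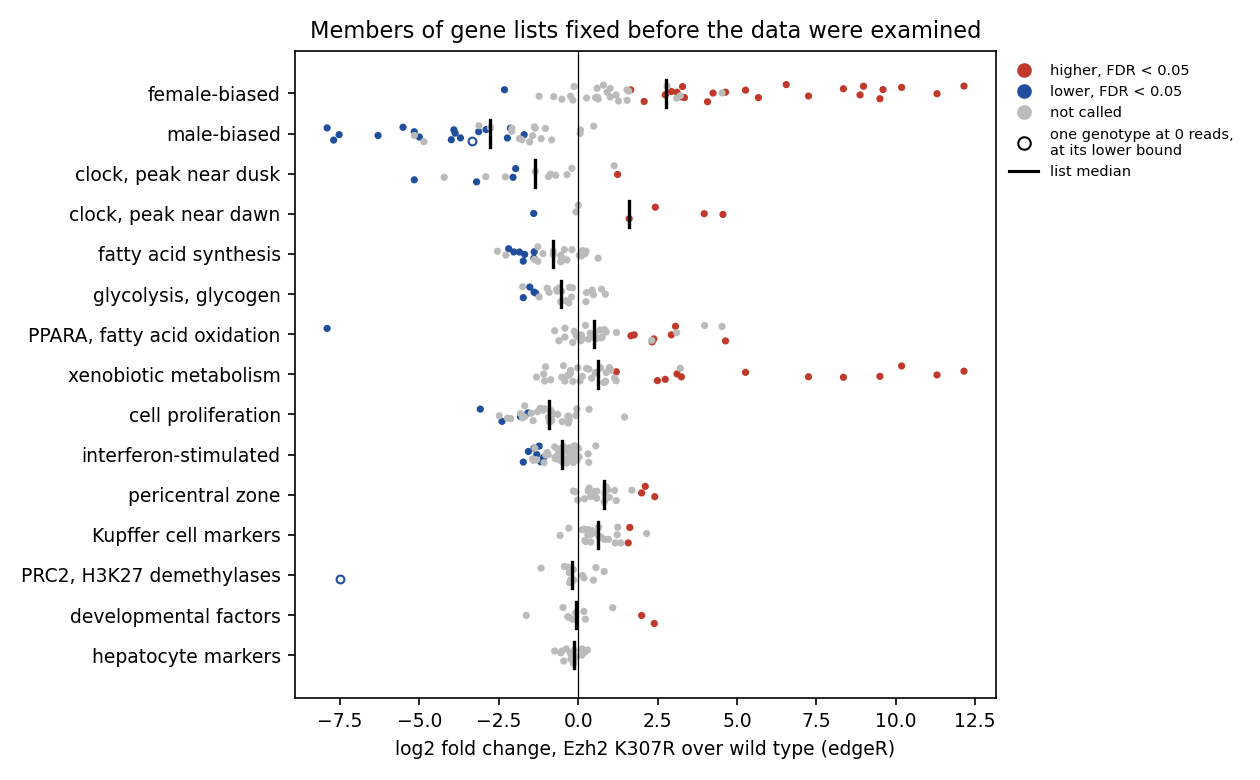
Log2 fold changes (mutant over wild type, 2 livers each) of the tested members of 15 gene lists; each point is a gene, red and blue points passed the edgeR test, grey points did not, open points are genes at 0 reads in a genotype drawn at their lower bound, and black lines are list medians. Medians run from -2.77 in the male-biased list to 2.77 in the female-biased list, and the hepatocyte marker median is -0.15.

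Proliferation genes were lower in the mutants, the livers with 0 reads of Ddx3y, Eif2s3y, Kdm5d and Uty. The 2 wild-type livers also differed widely in these genes, with a median log2 ratio of 0.91 for replicate 2 over 1 (on CPM + 1, 5 of 38 lower in replicate 2). Of 38, 4 fell and 0 rose in the mutants, and 10 fell when adjusted over the list alone. These were the replication genes Mcm10 (-1.82, SE 0.21) and Mcm6 (-2.40, SE 0.32), Ccne1, cyclin E1 (-3.09, SE 0.57), and Rrm2, a ribonucleotide reductase subunit (-1.58, SE 0.30). Ccne1 was at -2.46 without wild-type replicate 1. The median was -0.92 (camera adjusted p = 1.98e-08, adjusted p = 0.606 with an estimated correlation), with 3 of the 4 calls kept without mutant replicate 1 and 2 without mutant replicate 2. None of 22 cell cycle inhibitors and p53 targets was called by edgeR, in the whole test or over the list alone (0 of 22; median 0.20, mean -0.05, camera adjusted p = 0.697), against 5 at an unadjusted p under 0.05, 1 lower by DESeq2 and 0 by limma-voom. Of 19 fetal liver and imprinted growth genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone). Igf2bp3, a fetal RNA-binding protein, fell from 8.21 ± 1.24 to 0.417 ± 0.0108 CPM, and Lpl (-2.32, or -1.65 without wild-type replicate 2) and Tff3 (-5.67, or -6.44 and -3.85 without wild-type replicates 1 and 2) also fell. The list was lower (median -0.33, camera adjusted p = 0.00552, adjusted p = 0.562 with an estimated correlation), but not without wild-type replicate 2 (0.122) or with limma-voom (0.0785), with 2 of the 3 calls kept without mutant replicate 1 and 1 without mutant replicate 2. Of the 90 developmental transcription factors listed as textbook PRC2 targets, 11 had enough reads to be tested. Tbx3 rose by 2.0 (SE 0.33) and Lhx2 by 2.40 (SE 0.40), and Lhx6 had a log2 fold change of -1.64 (edgeR adjusted p = 0.0553), called without wild-type replicate 2 (-1.93, 0.00556); over the list alone 2 rose and 1 fell. The list did not pass the test (median -0.08, mean 0.26, camera adjusted p = 0.394). The call of Lhx2 was not kept without mutant replicate 1 (edgeR adjusted p = 0.075) or without mutant replicate 2 (0.115).

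As lists in the camera test at the preset correlation, interferon-stimulated genes were lower in the mutant livers, which also carried Xist. MHC class II and macrophage markers were higher there as lists. Of 49 interferon-stimulated genes, 7 fell and 0 rose, and 15 fell when adjusted over the list alone. Ifit3 (-1.30, SE 0.20), Usp18, which restrains interferon signalling (-1.73, SE 0.29), the virus-tethering protein gene Bst2 (-1.18, SE 0.20) and Irf7, a transcription factor of the interferon response (-1.23, SE 0.23), were among those that fell. The median was -0.52 (camera adjusted p = 1.38e-09, adjusted p = 0.419 with an estimated correlation). Without mutant replicate 1, 0 of the 7 calls were kept, without mutant replicate 2, 3 were kept, and without wild-type replicate 1, 6. All 10 MHC class II antigen presentation genes had log2 fold changes above 0 (median 0.89), and edgeR called 0 over all genes and 4 over the list alone. At an unadjusted p under 0.05 there were 6, DESeq2 called 2 higher and limma-voom 0. Cd74, the class II invariant chain, had 1.27 (edgeR adjusted p = 0.129) and H2-Aa 0.98 (0.13), and both were called without wild-type replicate 2 (2.03, 0.00106 and 1.48, 0.00632). The list was higher (camera adjusted p = 3.98e-04, adjusted p = 0.606 with an estimated correlation). Its genes also moved together between the 2 wild-type livers. Their median log2 ratio was 0.64 for replicate 2 over 1 (on CPM + 1, 0 of 10 lower in replicate 2). Of 24 Kupffer cell and macrophage markers, Cd163, the haptoglobin-haemoglobin receptor, rose by 1.58 (SE 0.26) and the ficolin gene Fcna by 1.62 (SE 0.29), and 7 rose when adjusted over the list alone (median 0.61, camera adjusted p = 3.99e-06, adjusted p = 0.638 with an estimated correlation). Neither call was kept without mutant replicate 1 (edgeR adjusted p = 0.103 and 0.0672), nor that of Cd163 without mutant replicate 2 (0.0666). Of 8 neutrophil markers, Il1b rose by 3.23 (SE 0.43), likewise over the list alone, and the list did not pass (camera adjusted p = 0.0697), though it was higher without mutant replicate 2 (0.00156) and at a mean of at least 1 CPM (0.0318). Of 30 acute phase genes, Serpina3m rose by 1.32 and the lipopolysaccharide-binding protein gene Lbp by 1.1, and Saa1 fell by 1.22 (3 and 5 adjusted over the list alone; median 0.07, mean 0.00, camera direction lower, adjusted p = 0.888). Serpina3m lost its call without mutant replicate 1 (edgeR adjusted p = 0.0681), Lbp without wild-type replicate 1 (0.0738) and without mutant replicate 2 (0.102), and Saa1 without mutant replicate 2 (0.123).

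Genes of the pericentral zone, the hepatocytes around the central vein, were higher in the Xist-bearing mutant livers. The 2 wild-type livers also differed in these genes, with a median log2 ratio of -0.62 for replicate 2 over 1 (on CPM + 1, 23 of 25 lower in replicate 2). Of 25, 3 rose and 0 fell in the mutants (9 and 0 adjusted over the list alone), namely Tbx3, the WNT target Axin2 (2.41, SE 0.46) and the ornithine aminotransferase gene Oat. The median was 0.82 (camera adjusted p = 4.37e-07, adjusted p = 0.578 with an estimated correlation), and 1 of the 3 calls was kept without mutant replicate 2, where Axin2 was at 1.70 (edgeR adjusted p = 0.148) and Oat lost its call (0.0877). Of 23 periportal genes, Ctsc rose by 1.69, Pigr by 1.40 and Gldc by 1.18, and Cdh1, E-cadherin, fell by 1.75 (5 and 1 adjusted over the list alone; median -0.08, mean 0.03, camera adjusted p = 0.738). The call of Pigr was not kept without mutant replicate 1 (edgeR adjusted p = 0.079) or 2 (0.0859), and that of Gldc was not kept without wild-type replicate 1 (0.0524) or mutant replicate 2 (0.0779). Of 24 genes of the growth hormone, insulin and IGF axis, Prlr, Irs2 and Stat5a (1.23, SE 0.25) rose and 0 fell (5 and 0 adjusted over the list alone), with Irs2 at 3.13, or at 2.37 without mutant replicate 2 and 3.82 without wild-type replicate 1. The list was higher (median 0.13, camera adjusted p = 0.0175, adjusted p = 0.562 with an estimated correlation), but not without mutant replicate 2 (0.0738) or on log2(FPKM + 0.1) (0.051). The call of Stat5a was not kept without wild-type replicate 2 (edgeR adjusted p = 0.0639) or without mutant replicate 2 (0.184). Of 37 coagulation and complement genes, C6 (-3.14) and C8b (-2.14), both also members of the male-biased list, and F11 (-1.01) fell (0 and 4 adjusted over the list alone; median 0.05, mean -0.25, camera adjusted p = 0.0586). C8b lost its call without mutant replicate 1 (edgeR adjusted p = 0.0597), and F11 without wild-type replicate 1 (0.0719), mutant replicate 1 (0.0933) or mutant replicate 2 (0.144). This list was lower without wild-type replicate 2 (camera adjusted p = 5.84e-04), with total-count scaling (0.0433) and with no filter (0.0397).

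Of 30 unfolded protein and integrated stress response genes, the asparagine synthetase gene Asns (-4.85, SE 0.85), Psat1, of serine synthesis (-2.83), and the mitochondrial folate enzyme gene Mthfd2 (-2.22) fell, and Vldlr, a lipoprotein receptor gene also in the female-biased list, rose by 3.29 (1 and 4 adjusted over the list alone, camera adjusted p = 0.368). This list was lower without wild-type replicate 1 (camera adjusted p = 0.00922) and without mutant replicate 2 (0.0435). The 3 falls were not kept without mutant replicate 1 or without mutant replicate 2 (0 of 3 in each). Asns was at -3.47 without wild-type replicate 2, -5.54 without wild-type replicate 1 and -5.65 without mutant replicate 1, where Psat1 was at -3.61. Of 22 immediate early genes, Dusp1 (-1.38), Zfp36 (-0.98) and Myc (-1.30) fell (4 and 1 adjusted over the list alone), and 2 of these 3 calls were kept without wild-type replicate 1, 1 without mutant replicate 1 and 0 without mutant replicate 2. The list was lower (median -0.16, camera adjusted p = 0.0447, adjusted p = 0.747 with an estimated correlation), but not without wild-type replicate 2 (0.517), mutant replicate 1 (0.0686) or mutant replicate 2 (0.0738), nor with limma-voom (0.0744), on log2(FPKM + 0.1) (0.0746) or with no filter (0.0743). With the replicate number as a block the immediate early list did not pass either. Of 17 heat shock chaperones, 0 were called by edgeR over all genes or over the list alone, 5 had an unadjusted p under 0.05, DESeq2 called 1 lower and limma-voom 0 (camera adjusted p = 0.948).

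Few markers of the cell types of liver were called. None of 15 hepatocyte markers (median -0.15, camera adjusted p = 0.283), 21 sinusoidal endothelial markers (0.21, 0.122), 14 cholangiocyte markers (0.08, 0.824), 14 T and NK cell markers (0.37, 0.281), 9 B and plasma cell markers (0.12, 0.888), 7 adipocyte and mesothelial markers or 6 gallbladder and intestinal markers (0.72, 0.132) was called by edgeR, and over the lists alone 2 adipocyte and mesothelial markers were lower and 2 gallbladder and intestinal markers higher. At an unadjusted p under 0.05 the counts in this order were 0, 4, 2, 3, 2, 2 and 3. DESeq2 called 1 B and plasma cell marker higher and 2 adipocyte and mesothelial markers lower and 0 in the other 5 lists, and limma-voom called 0 in all 7. The endothelial list was higher without wild-type replicate 2 (camera adjusted p = 0.0102) and without mutant replicate 1 (0.0427). The adipocyte and mesothelial list as a group was lower (median -0.89, camera adjusted p = 0.0447, adjusted p = 0.754 with an estimated correlation), but not without wild-type replicate 2 (0.771) or mutant replicate 2 (0.0738), with limma-voom (0.0785), on log2(FPKM + 1) (0.0809) and log2(FPKM + 0.1) (0.0822), with no filter (0.0565) or at a mean of at least 1 CPM (0.0517). Of 20 stellate cell and fibroblast markers, decorin, Dcn, rose by 1.36 and Colec11 by 1.5, while the type I collagen genes Col1a1 (-2.48) and Col1a2 (-1.72) fell (9 and 4 adjusted over the list alone). Without mutant replicate 1, Dcn (edgeR adjusted p = 0.0747), Colec11 (0.0814) and Col1a2 (0.0784) lost their calls, as did Col1a1 (0.105) and Col1a2 (0.124) without mutant replicate 2. Without wild-type replicate 2, Col1a1 was at -1.57 and Col1a2 at -1.11. This list was higher (median 0.80, camera adjusted p = 0.0245, adjusted p = 0.783 with an estimated correlation), but not without mutant replicate 1 (0.228) or on log2(FPKM + 1) and log2(FPKM + 0.1) (0.0964 and 0.147), and without wild-type replicate 1 the test gave the opposite direction (0.719). Of 35 extracellular matrix genes, Col4a2 (-1.28), Col1a1, Col1a2 and Col5a2 (-1.67) fell and 0 rose (8 and 2 adjusted over the list alone, median -0.26, camera adjusted p = 0.122), and 1 and 0 of these calls were kept without mutant replicates 1 and 2, and 3 without wild-type replicate 2. Without wild-type replicate 1 the matrix list was lower (camera adjusted p = 1.99e-07), and without wild-type replicate 2 the test gave the opposite direction (0.235). Of 10 erythroid markers, Alas2, the X-linked haem synthesis gene, fell by 1.94 (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.16), a call not kept without mutant replicate 1 (edgeR adjusted p = 0.0598). The erythroid list was higher without wild-type replicate 2 (camera adjusted p = 0.0319), with no filter (0.0362) and without the sex and clock genes (0.0137). Of 2 pancreatic acinar markers tested, the elastase gene Cela2a fell by 3.15, from 5.63 ± 0.0599 to 0.629 ± 0.311 CPM (-3.76 without mutant replicate 1), and over the list alone both were lower. The 1 muscle marker and the 4 replication-dependent histones tested gave 0 calls over all genes by edgeR, DESeq2 or limma-voom, and 1 histone, the 1 with an unadjusted p under 0.05, was higher over the list alone.

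The 76 cytosolic ribosomal protein genes had 0 calls by edgeR over all genes or over the list alone, 2 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom, and a median of -0.21 (camera adjusted p = 0.00525, adjusted p = 0.793 with an estimated correlation), but the list did not pass without wild-type replicate 1 (0.0564), and without mutant replicate 2 the test gave the opposite direction (0.588). Of 10 long nuclear RNAs, Xist rose and 0 fell (3 and 0 adjusted over the list alone). This list had a median of -0.20 and a mean of 0.95, with the test in the direction of the mean (camera adjusted p = 0.0112, adjusted p = 0.562 with an estimated correlation), and it did not pass without the sex and clock genes (0.944), without wild-type replicate 2 (0.105), with limma-voom (0.36) or on log2(FPKM + 1) and log2(FPKM + 0.1) (0.425 and 0.319). Of the 46 lists tested with camera at a preset correlation, 10 were higher and 14 lower. With a correlation estimated on 2 residual degrees of freedom, 0 of these calls held, and 4 of the 46 lists had an unadjusted camera p under 0.05. The fry test called 1 list higher, the long nuclear RNAs that include Xist (fry adjusted p = 0.0148), and 0 lower.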

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

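The fit without sex-chromosome, sex-biased list and clock list genes was the one chosen only after the results were seen, and the other alternatives were planned. With 178 genes higher and 189 lower in the main test, DESeq2 called 368 and 370, and edgeR with no filter on low counts 410 and 419. Limma called 94 and 69 on log2(FPKM + 1) and 91 and 70 on log2(FPKM + 0.1), and total-count scaling in edgeR gave 188 and 124. With 1 liver left out the counts ran from 117 to 327 higher and from 94 to 393 lower, lowest without mutant replicate 2 and highest without wild-type replicate 1. The cause of these differences was not tested, apart from the 10614 genes tested with FPKM, 13754 with DESeq2 and 17483 with no filter, against 12837. RLE and upper-quartile scaling, limma-voom, the stricter filter and the added fit kept both counts within 1.5 times. Genes shared with the 367 calls were 362 with DESeq2, 278 with total-count scaling, 286 with limma-voom, 151 with limma on either FPKM scale, and 171 to 336 with 1 liver left out. With the replicate number as a replicate block edgeR called 166 higher and 181 lower, 284 of them shared, and the major urinary protein (adjusted p = 0.0919) and immediate early lists (0.0514) lost their calls. The livers share only a replicate number in the labels, and the replicate differences of the genotypes correlated at -0.0027 across genes. Of 46 lists, 10 were higher and 14 lower in the main camera test, 0 and 0 with an estimated correlation (4 lists at an unadjusted p under 0.05), 1 and 0 with fry (11 at an unadjusted p under 0.05), and 8 and 9 in the added fit, where shared members had been removed. All other alternatives gave 7 to 12 higher and 10 to 15 lower, and DESeq2 was not run for lists. Ezh2 kept its sign and stayed uncalled in every alternative, with log2 fold changes from -0.51 to -0.08 and adjusted p from 0.708 to 0.974. Of the genes named in the text, 0 changed sign under any alternative that gave a value, and 53 values could not be had because a gene was filtered out. Calls that were lost numbered 43 without mutant replicate 2, 33 without mutant replicate 1, 44 and 42 with limma on FPKM, 16 with total-count scaling, 17 with limma-voom, 15 with the block, and 6 or fewer in each of the others. In the simulated comparison 2-fold changes were mostly missed, so that little can be said of smaller differences with these libraries. Neither depth nor the number of livers was varied in the simulation.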

Other observations

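The genes in this and the next paragraph, and all tests below except the count over other splits of the livers, were chosen only after the results were seen. Raet1d and Raet1e, which encode ligands of the natural killer cell receptor NKG2D, rose in the mutant livers by 3.10 (SE 0.21, edgeR adjusted p = 7.8e-04) and 3.37 (SE 0.28, 0.00156) on the log2 scale, and Xist was high in the same livers. Fzd7 and Fzd8, of the frizzled receptor family, rose by 1.30 (SE 0.20, edgeR adjusted p = 0.0197) and 1.5 (SE 0.20, 0.0116). Fzd7 lost its call with limma on the FPKM scales (adjusted p = 0.0541 and 0.0508).

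Among the genes that fell in the mutant livers, Coq7 and Coq10b, of coenzyme Q synthesis and transport, had log2 fold changes of -1.30 (SE 0.19) and -1.6 (SE 0.18), and Nampt and Nmrk1, which feed the salvage of NAD, had -1.29 (SE 0.19) and -1.34 (SE 0.23). Their edgeR adjusted p values were 0.0171, 0.0066, 0.0177 and 0.0288. Coq7 lost its call without mutant replicate 1 (0.0506) or replicate 2 (0.0513), Nampt without mutant replicate 2 (0.0714) and Nmrk1 without mutant replicate 1 (0.0858), with total-count scaling (0.0543) and with limma on the FPKM scales (0.0818 and 0.0835). These genes were picked singly, and neither pathway was tested as a group.

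Xist and 4 Y-linked genes separated the genotypes, and the point mutation acting in animals of one sex is argued against by 0 reads of these 4 genes in both mutant livers together, against 5283 in the wild type. The values are consistent with wild-type males and mutant females, since 73 of 83 autosomal genes of the sex-biased lists (87.95%) moved in the direction that sex would give, 41 of 48 female-biased ones up and 32 of 35 male-biased ones down. Both livers of a genotype could also have been exchanged for animals of another origin, which would change what every difference here means, and the counts do not read the mutation (Ezh2 log2 fold change -0.281), so that this cannot be told apart. The 298 calls outside the sex-chromosome, sex-biased and clock genes cannot be told apart from effects of sex, because each genotype had 1 sex-chromosome pattern. Nor can they be told apart from whatever shifted the clock genes, which also differed between the genotypes. Only genes on the sex chromosomes and in these lists were removed, so other genes that follow sex or the clock may remain. An effect of the mutation on the 298 stays open and untested. Of the 3 splits of the livers into 2 and 2, 1 gave 367 calls or more, the real one, and the highest of the others gave 0 by edgeR (243 and 172 genes at an unadjusted p under 0.05), but 3 splits are too few for a share under 0.05. The other splits also put 1 liver of each genotype in both groups. The genotype difference then adds to the spread within groups, so their 0 calls do not bear on the real split.

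The clock genes moved in opposite directions by peak time. A shift of all genes between the libraries would move both lists by the same amount, but the median of the dawn genes lay 2.957 above that of the dusk genes on the log2 scale, which argues against it. Livers taken at another phase of the day may account for the pattern, with 5 of 7 dawn genes above 0 and 13 of 15 dusk genes below 0. So large a difference of the medians is rare when the genes are relabelled (exact permutation test over all 170544 relabellings of the 22 genes, two-sided, p = 0.00478, with genes not independent). That test measures the same opposite movement and does not tell phase of the day from other causes. Nr1d1, in the dusk list, rose against its list. An effect of sex, of feeding or of the mutation on the clock stays open, since no label gives the hour of collection.

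The major urinary proteins took a 4.959 times larger share of the counts in wild-type replicate 1 than in replicate 2. Reads divided differently between near-identical copies would leave this family total alike, depth differed by 1.039 times, and Xist in wild-type replicate 2 was at 0.0631% of the mutants' mean, which argues against copies, depth and admixed female RNA. A weaker male-type programme in wild-type replicate 2 is a candidate explanation, since the 30 other male-biased genes had a median log2 ratio of -1.192 between replicates 2 and 1 (29 lower), below the medians of all 44 other fixed lists with at least 5 genes (-0.62 to 0.91), with genes not independent and 1 liver on each side. The 48 female-biased genes had a median of 0.72 (8 lower), but 4 of these lists lay higher, among them cell proliferation (0.91) and extracellular matrix (0.83), so that these livers differed in more than this programme. Between the mutant livers, replicate 2 over 1, these medians were 0.28 and -0.19, and age, social rank or housing, which the labels do not give, were not tested. The family's share in wild-type replicate 2 (0.904%) also lay below those of the mutant livers (1.27% and 1.46%), which carried the female-type transcripts. A weaker male-type programme would bring the share towards that level, not under it, so by itself it leaves this part unexplained.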
